A study of Homo sapiens and Mus musculus with 4 samples.

How the data were processed

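Poly(A) messenger RNA was sequenced from HaCaT and SCC7 cells with and without aged garlic extract (AGE). Per the labels' protocols, total RNA was purified on silica columns, messenger RNA was captured with oligo-dT, libraries were made with a NEBNext Ultra II kit, and paired-end reads were sequenced on a NovaSeq instrument. Each library is a group of its own, with the group taken from its sample title.

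Each deposited file lists 1 library. The HaCaT files hold 57773 human genes and the SCC7 files 41325 mouse genes. The authors deposited counts per gene of exon, intron and exon-exon junction reads, each as total and uniquely mapped reads, per the file headers. The deposited TPM column equals total exon reads over exon length, scaled to the same sum in each library, and the expression value column repeats it. The deposited RPKM column divides total exon reads by exon length and by a library total that exceeds the sum of gene reads (45335902, 42193104, 38274255 and 47772576 for HaCaT with AGE, untreated HaCaT, SCC7 with AGE and untreated SCC7, as implied by the values). The RPKM values were not used further. The genome build is GRCh37 per the submitters' processing notes, for all 4 libraries. The human coordinates are given in it. The SCC7 files hold mouse genes, whose build was not given in the sources used here, so no mouse coordinates are printed. The aligner, the counting tool and their versions were not given in the sources used here, nor whether strand was used, so overlapping genes and near-identical copies can share reads.

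Counts of total exon reads were the main values, since the deposited TPM is built on them. The plan spoke of all reads of a gene, and exon plus intron reads were added as an alternative after the columns were seen. Effective library sizes were set by TMM in edgeR 4.0.16 (R 4.3.3), and DESeq2 1.42.0 gave size factors for an alternative. Ratios and intervals were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. CPM is the scaled count that edgeR defines, taken on exon reads and the effective library size. Genes with a CPM of 1 or more in either library of a line were tested. The log2 ratio of AGE over untreated used a prior count of 1. A gene counted as higher or lower where it was at least 2-fold apart and the exact 95% interval of the ratio (Clopper-Pearson on the AGE library's share of its reads) excluded equality. Even counts made up 71.0% to 78.8% of counts from 2 to 20 in the 4 libraries, so both mates of a pair appear to be counted. Intervals printed here are therefore those of pairs (counts divided by 2), while the calls use the interval on reads as planned. Counts, intervals and floors do not account for PCR copies or for differences between cultures. A library of this depth has a floor of 3 reads, which is a CPM (over all exon reads) of 0.0788 in HaCaT with AGE, 0.0761 in untreated HaCaT, 0.0843 in SCC7 with AGE and 0.0675 in untreated SCC7.

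With 1 library per group no test between conditions is possible. The number of genes that counting noise alone would call was taken from 100 simulations that drew both libraries, in pairs of reads, from their pooled proportions. For 35 gene lists fixed before the data were examined (30 pathways or gene families and 5 sets of cell type markers), the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart outside the central 95% of them, and 3 measured genes were needed. The percentile describes these libraries only. Genes of a list can vary together for reasons other than AGE, so more lists than the number given for independent genes can stand apart. Of 626 human and 619 mouse symbols, 625 and 618 were found. For 6 mouse symbols the name used in the files was set by hand after they were read, human names were also sought through a reference table holding 51996 of the 57773 human gene IDs, and where a name carries a number suffix the lowest gene ID was taken.

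Genes are named by a rule fixed in advance: in each line the 12 higher and 12 lower genes whose interval lies farthest from equality, among genes with a CPM of 5 or more in either library, then up to 4 members of each list past 2-fold or otherwise its highest and lowest member, then up to 10 genes past 2-fold in both lines. Highest and lowest members are given only for lists that stood apart, which departs from the rule for length, and some further members of those lists were chosen after their values were seen. A second ranking of protein-coding genes with 90% or more unique reads was also chosen after the values were seen.

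The code was tested on simulated data with 200 changed genes per line. Reads were drawn in pairs, so the simulated counts were all even, unlike those of the libraries. The coverage below therefore checks the code and not the pairing of reads in the libraries. The intervals on pairs held the true ratio for 95.2% of 13478 genes in HaCaT and 95.3% of 11874 in SCC7, and those on reads as deposited for 83.6% and 83.2%. Of genes made 3-fold apart, 98% in HaCaT and 100% in SCC7 were called, of those 4-fold apart 100% and 98%, and of those 1.5-fold apart 6% and 0%. With no change simulated, 2 of 33 HaCaT lists and 2 of 31 SCC7 lists stood apart.

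Alternatives were other scalings (DESeq2 size factors, total counts, TMM without the 50 most abundant genes), other filters on low counts, other prior counts, a 1.5-fold threshold, the deposited TPM with a pseudocount of 1, uniquely mapped reads and protein-coding genes only. Others were added after the data were seen: exon and intron reads, genes with 90% or more unique reads, junction reads only, a 1.25-fold threshold and the interval on pairs. On TPM no interval was required, and genes with a TPM of 1 or more in either library were tested. Expression of genes in other cells or at other doses was not analysed here.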

Results

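Messenger RNA was sequenced from a human and a mouse cell line, each grown with or without aged garlic extract (AGE), a preparation made by long storage of garlic in aqueous ethanol. HaCaT is a spontaneously immortalised human keratinocyte line that does not form tumours, and SCC7 is a mouse squamous cell carcinoma line. The series asks how AGE acts in these cells and whether it acts differently in normal and in cancer cells. The 4 libraries fall into 4 groups with 1 library each: HaCaT with AGE, untreated HaCaT, SCC7 with AGE and untreated SCC7. The dose and the length of treatment were not given in the sources used here. The libraries held 38078659 exon reads (HaCaT with AGE), 39415748 (untreated HaCaT), 35581150 (SCC7 with AGE) and 44445685 (untreated SCC7). Because no group has a replicate, no difference given here has a replicate check, and no p-value is given. The 95% intervals cover counting error only. A gene or list called higher or lower was so in the AGE library against the untreated library of the same line.

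In HaCaT, the AGE library differed from the untreated library by small amounts in groups of genes. Targets of NRF2, the transcription factor of the antioxidant response, were lower, with a median log2 ratio of -0.12 over 24 genes, 19 of which had intervals below equality. SLC7A11, the cystine transporter (-0.29, interval -0.38 to -0.20) and TXNRD1, a thioredoxin reductase (-0.22, -0.27 to -0.16), were among them. Genes of the ATF4 amino acid response were lower as well, with a median of -0.14 over 20 genes and 12 intervals below equality. The 13 mitochondrially encoded genes were all higher, with a median of 0.20, in a library that also held more mitochondrial ribosomal RNA (0.926% of exon reads against 0.681%).

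Within the HaCaT ATF4 list, the serine and one-carbon enzymes PSAT1 (-0.32, -0.38 to -0.26), PSPH (-0.38, -0.56 to -0.19) and MTHFD2 (-0.35, -0.47 to -0.23) and the asparagine synthetase ASNS (-0.34, -0.46 to -0.22) were among the lower members, as was CHAC1, which degrades glutathione (-0.38, -0.71 to -0.06). PSAT1 lies on chromosome 9 at 80912059 to 80945009 and ASNS on chromosome 7 at 97481430 to 97501854 (GRCh37). ATF4 itself had a log2 ratio of -0.01 (-0.06 to 0.04), and ATF3, also an immediate early gene, was the highest member at 0.24 (0.04 to 0.43). NUPR1 was the lowest at -0.40, with an interval that includes equality (-0.92 to 0.10). Among NRF2 targets the highest was the heme oxygenase HMOX1 at 0.04 (-0.76 to 0.84). Other members included the aldo-keto reductase AKR1C2 (-0.21, -0.23 to -0.18) and the ferritin light chain FTL (-0.16, -0.20 to -0.13).

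Both medians lay below all 10000 random lists of the same size matched on expression, which describes these libraries alone. Of 33 lists with enough measured genes in HaCaT, 12 stood apart from random lists, where 1.65 would lie outside the limits if genes varied independently. The other lower lists had smaller medians. Fatty acid synthesis had -0.07 (percentile 0.170), with FASN at -0.10 (-0.12 to -0.08), FADS1 lowest at -0.13 (-0.20 to -0.05) and FADS2 highest at 0.16 (-0.12 to 0.44). The p53 targets had -0.07 (percentile 0.525), from the BTG2 value of 0.09 (-0.03 to 0.20) to the SESN1 value of -0.34 (-0.65 to -0.03). Heat shock genes had -0.05 (percentile 1.27), with HSPE1 lowest at -0.15 (-0.25 to -0.06) and HSPA1A highest at 0.04 (0.01 to 0.08). Glycolysis and hypoxia genes had -0.04 (percentile 0.850). In that list the carbonic anhydrase CA9 was past 2-fold at -1.0 (-2.0 to -0.11) and the demethylase KDM3A was highest at 0.20 (0.07 to 0.33).

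Among higher HaCaT lists, the immediate early genes had a median of 0.09, above all random lists, with 9 of 25 intervals above equality and 1 below. FOSB was highest (0.53, 0.39 to 0.68), FOS was at 0.18 (0.13 to 0.24), MYC at 0.16 (0.10 to 0.22) and SPRY4 lowest at -0.20 (-0.83 to 0.42). Keratinocyte differentiation genes had a median of 0.07 (percentile 99.3), and S100A7, a psoriasin of inflamed epidermis, was past 2-fold at 1.18 (0.62 to 1.78). The suprabasal keratins KRT4 (0.47, 0.40 to 0.54) and KRT13 (0.26, 0.22 to 0.30) were higher, KRT1 was lower (-0.09, -0.16 to -0.02), and ZNF750 had the lowest value, -0.59 (-1.57 to 0.33). Replication-dependent histone genes had 0.25 (percentile 99.9), with HIST1H1E at 3.45 (2.49 to 4.79) and HIST2H2AC at 1.44 (0.19 to 3.0) past 2-fold. DNA replication and S phase genes had 0.04 (percentile 98.5), with 2 intervals above equality among 22, E2F1 highest at 0.33 (0.18 to 0.49) and CCNE1 lowest at -0.13 (-0.54 to 0.27). Ribosomal protein genes had 0.02 (percentile 98.6), from the RPL13 value of 0.05 (0.02 to 0.07) to the RPS15 value of -0.07 (-0.11 to -0.02). Of these 30 genes, 3 had intervals above equality and 2 below. The mitochondrially encoded genes ran from MT-CO2 at 0.33 (0.31 to 0.34) to MT-ND4L at 0.13 (0.07 to 0.20).

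On the deposited TPM values, the median log2 ratio of all HaCaT genes was -0.15. On that scale the medians of the S phase (-0.12), immediate early (-0.07), keratinocyte differentiation (-0.02) and ribosomal protein (-0.14) lists fell below 0 while staying above the median of all genes, and the ribosomal protein list no longer stood apart. With reads across exon-exon junctions only, the calls of the heat shock, p53, S phase, glycolysis and hypoxia, immediate early, ribosomal protein and histone lists ended, and that of fatty acid synthesis ended when genes with under 90% unique reads were left out. Junction reads were fewer than exon reads (12731347 against 38078659 with AGE), so a call can end for lack of reads. Of 16 histone genes past 2-fold higher, 15 had under 10 junction reads, so junction reads say little about that list.

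The other lists tested in HaCaT lay inside the random range, though EMT genes, ER chaperones and metallothioneins lay outside it in some alternatives. Their medians were 0.0060 for glutathione and peroxide enzymes, -0.04 for ER chaperones, 0.09 for metallothioneins, -0.03 for mitosis, -0.0084 for apoptosis regulators, -0.02 for cholesterol synthesis, -0.03 for interferon-stimulated genes and -0.0077 for inflammatory cytokines and NF-kB targets. They were -0.03 for basal keratinocyte genes, -0.01 for tight junctions and desmosomes, 0.03 for mesenchymal and EMT genes, -0.01 for TGF-beta targets, 0.04 for Wnt and Notch targets, 0.02 for AHR and xenobiotic genes, 0.0095 for autophagy and lysosome, 0.0091 for oxidative phosphorylation, 0.01 for ribosome biogenesis and 0.00076 for ferroptosis and iron. Marker lists had 0.10 for fibroblasts and 0.09 for immune cells, on 3 measured genes each, and -0.03 for keratinocytes. Endothelial and melanocyte markers had 2 measured genes each and were not tested.

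**Figure D1:**
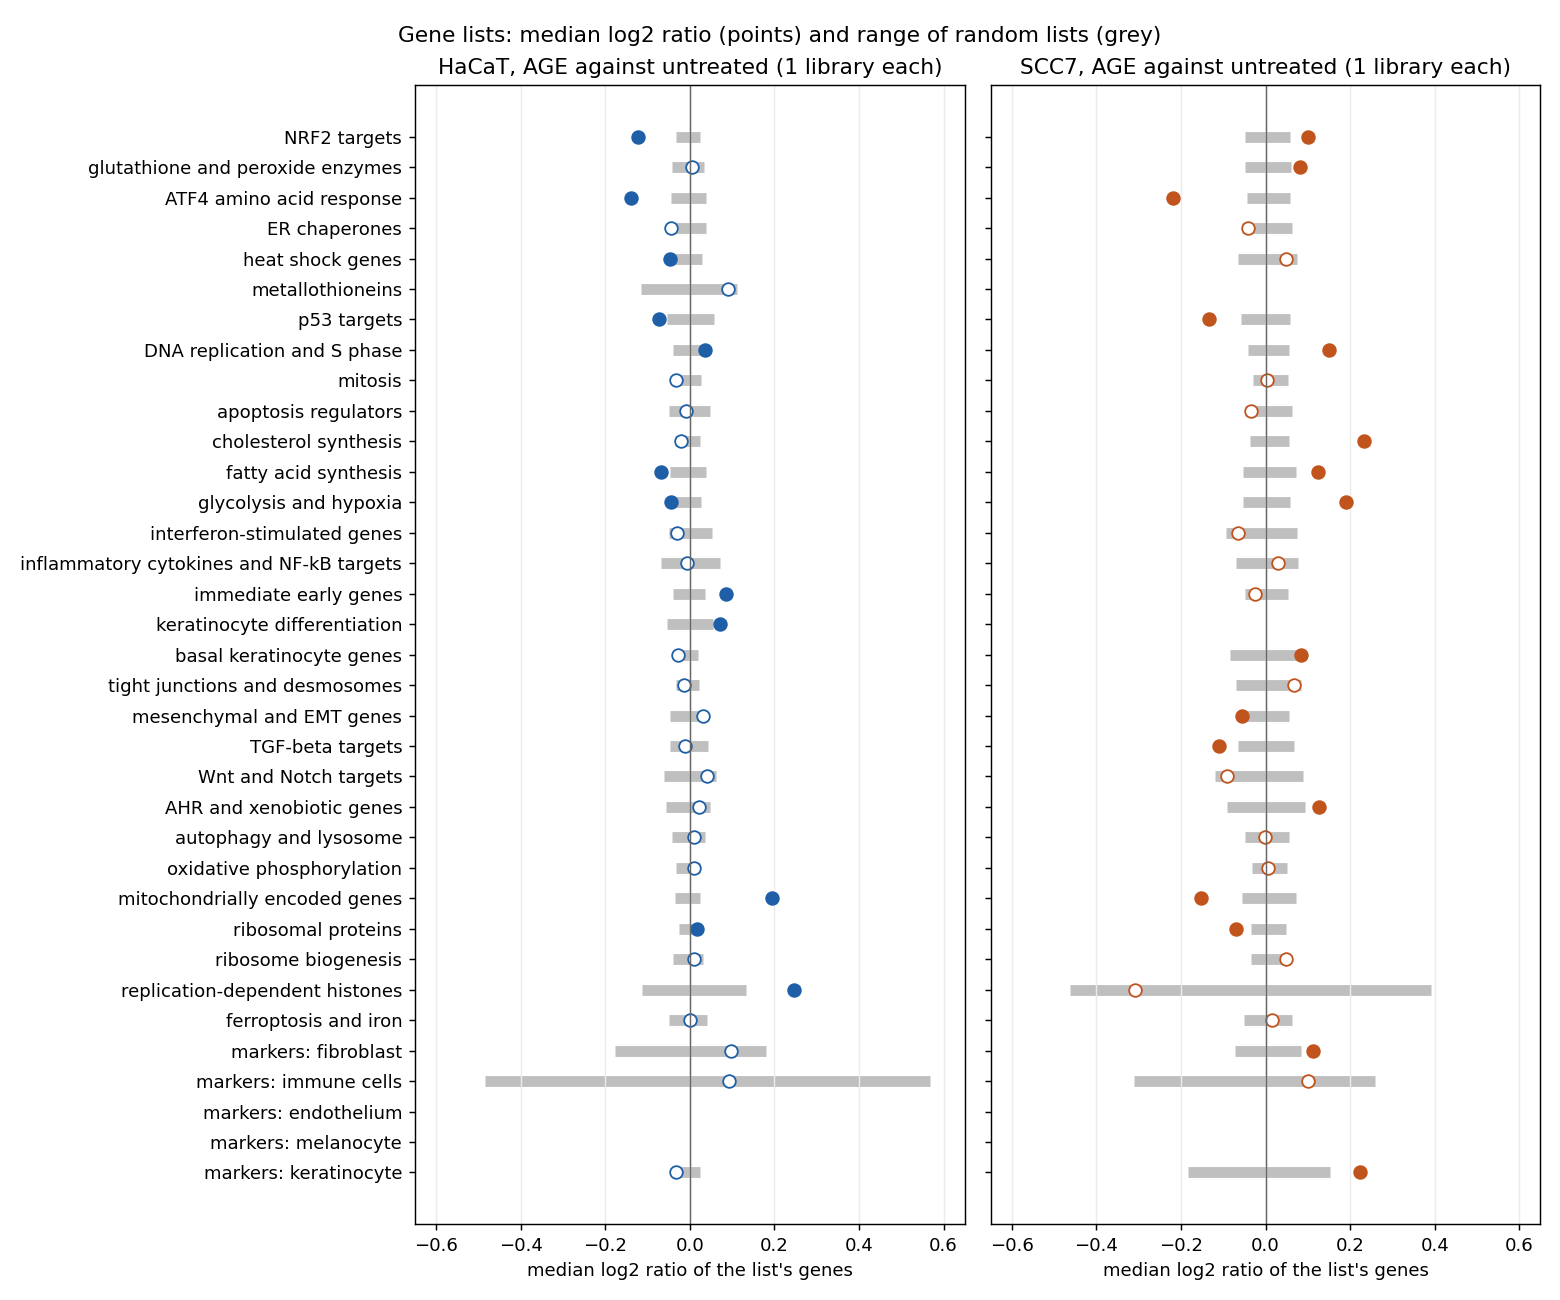
Each point is the median log2 ratio (AGE over untreated) of a gene list fixed before the data were examined, in HaCaT (left) and SCC7 (right), and the grey bar spans the central 95% of 10000 random lists matched on expression. Filled points stand outside the bar, open points inside it. NRF2 targets lie at -0.12 in HaCaT and 0.10 in SCC7, while the ATF4 list lies at -0.14 and -0.22.

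Gene by gene, 220 of 13532 tested HaCaT genes differed at least 2-fold with an interval excluding equality, 146 higher and 74 lower. Counting noise alone gave a mean of 49.4 such genes in simulations. The genes ranked highest by their interval were mostly RNAs that carry no poly(A) tail. RPPH1, the RNA of RNase P (chromosome 14 at 20811207 to 20811844), had 2472 exon reads with AGE and 30 without, a log2 ratio of 6.38 (5.70 to 7.27). RMRP, the RNA of RNase MRP, had 5.57 (5.02 to 6.25), and RN7SK, the RNA that holds P-TEFb inactive, 4.79 (4.41 to 5.22). The genes RNA5-8SP2, RNA5-8SP3, RNA5-8SP5, RNA5-8SP6, AC010970.2 and CTD-2328D6.1 resemble ribosomal RNA and were higher by 3.98 to 5.48. CTD-2328D6.1 alone had 209620 reads with AGE and 13948 without. RNU2-2P, named as a U2 small nuclear RNA gene, had 194 reads with AGE and 0 without, at least 67.7-fold higher against a floor of 3 reads and 27.0-fold by the lower end of the interval on pairs, but none of its reads mapped uniquely. The remaining genes of the top 12 were AP000318.1, annotated as a microRNA (4.26, 3.89 to 4.67), and AL591684.1, with 221 reads against 0 and at least 77.1-fold higher against that floor and 30.8-fold by the interval on pairs, again with no unique reads. As a share of exon reads, these 6 ribosomal RNA-like genes took 0.745% with AGE and 0.0453% without, and 5 RNA polymerase III genes 0.0656% and 0.00971%. All 6, and RPPH1, RMRP and RN7SK of the other 5, were among the 12 ranked highest. Their shares are therefore no separate check of the difference. In SCC7 the shares were 0.465% and 0.510%, and 0.00219% and 0.00231%. There the ribosomal RNA-like genes were CT010467.1 and n-R5-8s1, which are not the same set. Intron reads made up 10% of gene reads in the HaCaT AGE library and 5.20% in the untreated one, against 5.44% and 5.33% in SCC7.

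**Figure D2:**
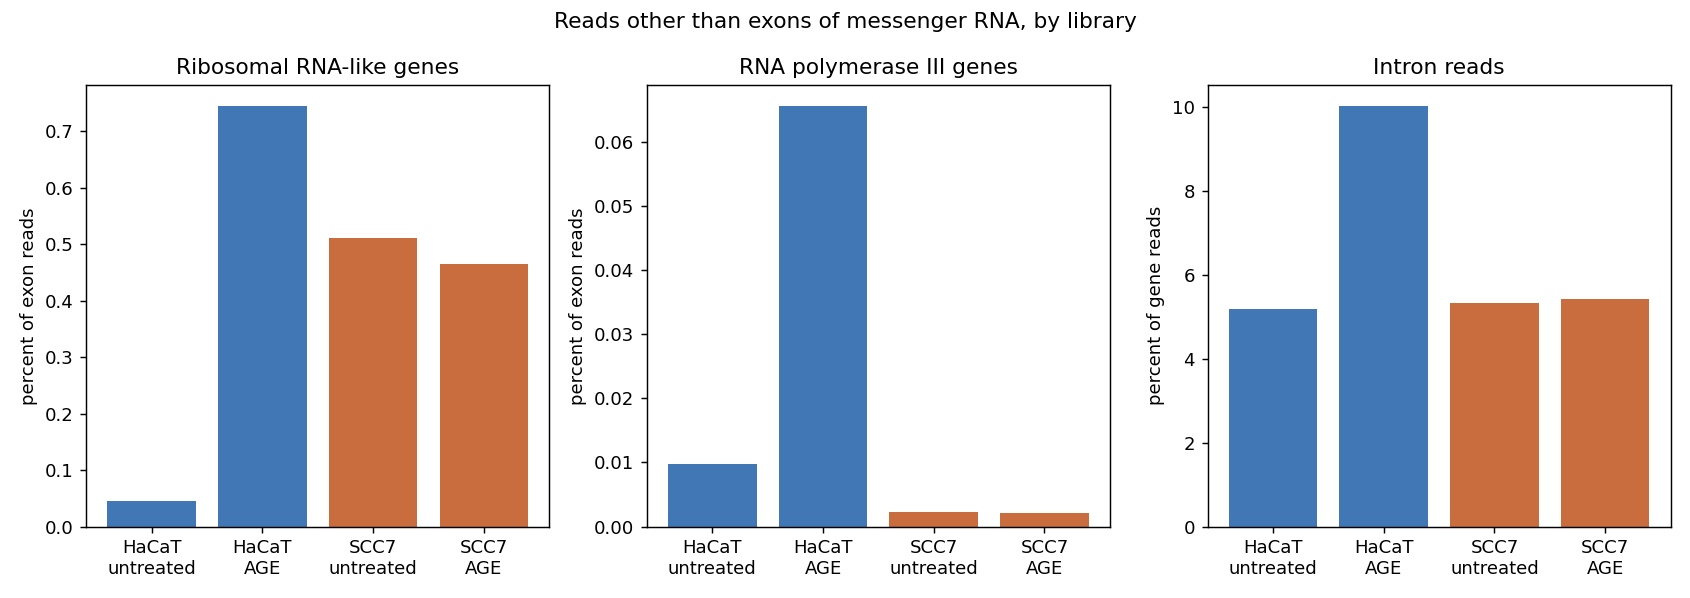
Bars give, for each of the 4 libraries, the percent of exon reads on ribosomal RNA-like genes (left) and on RNA polymerase III genes (middle), and the percent of gene reads that lie in introns (right). The HaCaT AGE library stands above untreated HaCaT in all 3, at 0.745% against 0.0453%, 0.0656% against 0.00971% and 10% against 5.20%. All the HaCaT ribosomal RNA-like genes, and RPPH1, RMRP and RN7SK of the polymerase III genes, were among the 12 ranked highest.

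Among HaCaT genes ranked lowest, AC099522.1 (-5.18, -7.23 to -3.96), FAM203B (-4.87, -6.65 to -3.75) and RP4-781K5.2 (-4.14, -5.72 to -3.08) had almost no uniquely mapped reads. RP4-669L17.10, AC005280.1, ISY1-RAB43, TEN1-CDK3, KCTD7, RGPD5 and AC005618.1 followed at -1.47 to -0.77, each with a share of unique reads below 90% in 1 library or both. Reads of such genes can be split among near-identical or overlapping copies, so their values are uncertain, and KCTD7 was higher (0.24) on uniquely mapped reads alone. Of the 12, only MMP1 and IGFN1 had nearly all reads unique. MMP1, the interstitial collagenase (chromosome 11 at 102660651 to 102668891), had 1530 reads with AGE and 2405 without (-0.59, -0.72 to -0.45), and IGFN1 had -0.72 (-1.15 to -0.31).

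A second ranking, chosen after the values were seen, kept protein-coding genes with at least 90% unique reads. Its highest HaCaT genes were SHC3, an adaptor protein (4.07, 3.79 to 4.37), FEZF2, ANKRD30BL, RASSF4, GPR64, ASTN1, KLF15, FAF1, FGF2, SYNGR3, SCGB1A1 and S100A8. In most of them few of the added reads crossed exon junctions. FEZF2, ANKRD30BL, GPR64, ASTN1 and KLF15 had no junction reads in either library and RASSF4 2 in each. ANKRD30BL spans the ribosomal RNA-like gene RNA5-8SP5 on chromosome 2. SHC3 had 3473 exon reads with AGE and 216 without but 3 and 0 junction reads, and FAF1 had 14830 and 3290 exon reads but 1279 and 1347 junction reads, while SYNGR3 had 18 and 36. The fibroblast growth factor gene FGF2 had 1.30 (1.01 to 1.60), with 27 and 11 junction reads. SCGB1A1, a secretoglobin of airway epithelium, had 0.71 (0.56 to 0.85), with 573 and 377. On the lower side MMP1 and IGFN1 were followed by FBN2, a fibrillin of elastic fibres (-0.48, -0.65 to -0.30), SH3TC1, PLEKHG1, GNAI1, PSAT1, UBASH3B, PIP5KL1, MTHFD2, ASNS and BNIP1, so 3 genes of the ATF4 list were among the 12. Of the 220 genes, 60.5% had under 90% unique reads, against 17.3% of all tested genes. On the deposited TPM values 297 genes were higher and 281 lower, so the share of higher genes was 51.4% instead of 66.4%. That setting is looser, as it required no interval and tested 15328 genes.

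**Figure D3:**
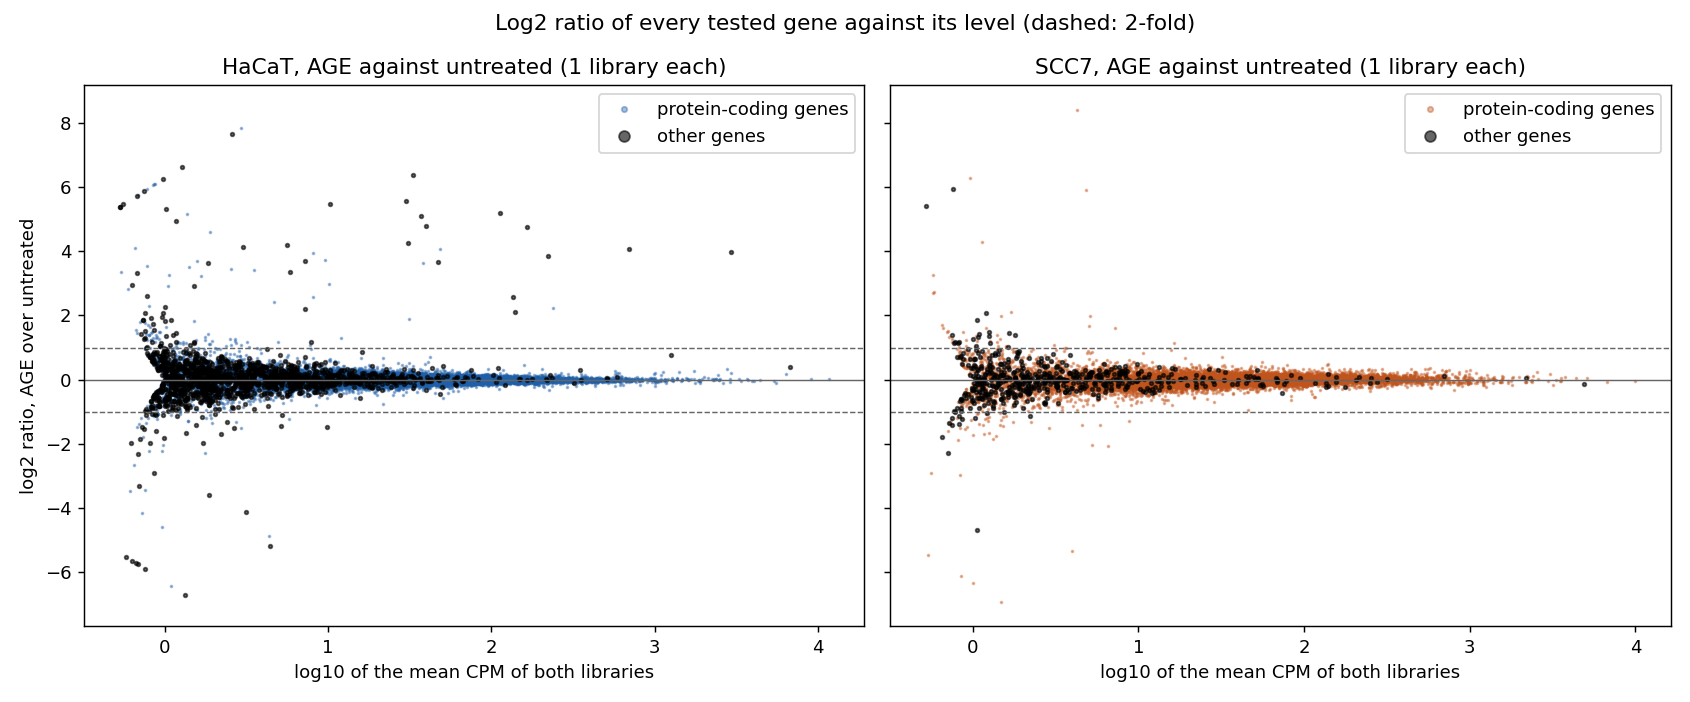
Each point is a tested gene, with the log10 of its mean CPM on the horizontal axis and its log2 ratio (AGE over untreated) on the vertical axis, for HaCaT (left) and SCC7 (right). Genes annotated as protein-coding are coloured, others are black, and dashed lines mark 2-fold. Among genes with a CPM of 5 or more, the standard deviation of the log2 ratio is 0.27 in HaCaT and 0.19 in SCC7.

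In SCC7, the AGE library had higher levels of genes of cholesterol synthesis, glycolysis and DNA replication and lower levels of ATF4 response genes. The cholesterol synthesis list had a median log2 ratio of 0.23, with all 20 genes above 0 and 19 intervals above equality. The lanosterol synthase Lss (0.48, 0.40 to 0.55) and the mevalonate pathway enzyme Mvd (0.41, 0.29 to 0.53) were highest, and Srebf2 was lowest at 0.09 (0.07 to 0.12). The ATF4 list had a median of -0.22, with 16 of 21 intervals below equality. Trib3, a pseudokinase (-0.63, -0.74 to -0.53), the stress factor Ddit3 (Ddit3_1 in the files, -0.62, -0.81 to -0.43) and Chac1, a glutathione-degrading enzyme (-0.51, -0.61 to -0.41), were among its lower members.

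Glycolysis and hypoxia genes in SCC7 had a median of 0.19, with 16 of 23 intervals above equality and 1 below. The carbonic anhydrase Car9 was highest (0.82, with a lower bound of 0.41), the glycolytic enzymes Pgk1 (0.30, 0.27 to 0.33) and Ldha (0.29, 0.25 to 0.32) were higher, and the prolyl hydroxylase Egln3 was lowest (-0.81, -1.57 to -0.12). DNA replication and S phase genes had 0.15, with 15 of 22 intervals above equality. In that list Ccne1 was highest (0.42, 0.14 to 0.71), Pcna was at 0.16 (0.11 to 0.22), Mcm6 at 0.15 (0.11 to 0.20) and Slbp lowest at -0.05 (-0.16 to 0.06). NRF2 targets had 0.10, with 11 of 21 intervals above equality and 2 below, from Gclm, a subunit of the enzyme that starts glutathione synthesis (0.24, 0.10 to 0.37), to Akr1c12 (-0.51, -0.84 to -0.18). These 3 medians and that of cholesterol synthesis lay above all 10000 random lists, and the ATF4 median below all of them. Within the ATF4 list the hormone gene Fgf21 was lowest (-0.95, -1.51 to -0.42) and Stc2 highest (0.09, -0.16 to 0.34).

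Of 31 SCC7 lists with enough genes, 16 stood apart, where 1.55 would lie outside the limits if genes varied independently. Fatty acid synthesis had 0.12 (percentile 99.9), with Elovl6 highest at 0.33 (0.27 to 0.39), Fasn at 0.27 (0.24 to 0.30) and Srebf1 lowest at -0.05 (-0.12 to 0.03). The p53 targets had -0.13, below all random lists, with 9 of 20 intervals below equality. Btg2 was lowest at -0.39 (-0.53 to -0.26), Cdkn1a was at -0.17 (-0.23 to -0.12) and Gdf15 was highest at 0.27 (-0.51 to 1.06). Mitochondrially encoded genes had -0.15, below all random lists, with 12 of 13 intervals below equality, from mt-Cytb at -0.24 (-0.27 to -0.22) to mt-Nd2 at -0.04 (-0.09 to 0.00). Ribosomal protein genes had -0.07 (percentile 0.0200), with 26 of 30 intervals below equality, Rpl32 lowest at -0.15 (-0.18 to -0.12) and Rpl27 highest at 0.10 (-0.01 to 0.21). TGF-beta targets had -0.11 (percentile 0.0700), with Tgfb2 lowest at -0.40 (-0.66 to -0.15) and Id2 highest at 0.20 (-0.18 to 0.58). Mesenchymal and EMT genes had -0.06 (percentile 1.77), with the smooth muscle actin Acta2 lowest at -0.93 (-1.08 to -0.79) and the collagenase Mmp13 highest at 0.37 (0.16 to 0.59). That list was mixed, with 9 of 23 intervals below equality and 6 above.

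Glutathione and peroxide enzymes in SCC7 had 0.08 (percentile 99.6), from the Mgst1 value of 0.27 (-0.02 to 0.56) to the Gss value of -0.05 (-0.23 to 0.12), and Prdx1, a peroxiredoxin, had 0.14 (0.09 to 0.18). AHR and xenobiotic genes had 0.13 (percentile 99.5), with Aldh3a1 highest at 0.35 (0.15 to 0.54), Nqo1, also an NRF2 target, at 0.23 (0.09 to 0.36) and Cyp1b1 lowest at -0.40 (-1.15 to 0.31). Basal keratinocyte genes had 0.08 (percentile 98.6, 14 of 20 genes measured), keratinocyte markers 0.22 (percentile 99.5, 7 of 15) and fibroblast markers 0.11 (percentile 99.5, 8 of 12). In the same order, the intervals above and below equality numbered 6 and 2, 2 and 1, and 4 and 2. The basal list and the keratinocyte markers share Krt14 (0.77, -0.21 to 1.81) and Trp63 (-0.82, -1.29 to -0.37), their highest and lowest members. Of the keratinocyte markers the simple epithelial keratins Krt18 (0.33, 0.27 to 0.38) and Krt8 (0.32, 0.28 to 0.36) had intervals above equality. Of the fibroblast markers Dcn was highest (0.42, 0.29 to 0.54) and Pdgfrb lowest (-0.12, -0.27 to 0.02). With junction reads only, the TGF-beta and AHR medians changed sign (0.02 and -0.10), and the calls of the glutathione, basal keratinocyte, EMT, fibroblast marker and keratinocyte marker lists ended. The AHR and glutathione calls also ended when genes with under 90% unique reads were left out, the AHR call on uniquely mapped reads, and the basal, EMT and keratinocyte marker calls on the deposited TPM values.

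The SCC7 lists inside the random range, of which Wnt and Notch targets, interferon-stimulated genes and histones lay outside it in some alternatives, had medians of -0.04 for ER chaperones, 0.05 for heat shock genes, 0.0046 for mitosis, -0.04 for apoptosis regulators, -0.07 for interferon-stimulated genes, 0.03 for inflammatory cytokines and NF-kB targets, -0.02 for immediate early genes and 0.07 for tight junctions and desmosomes. They were -0.09 for Wnt and Notch targets, -0.00067 for autophagy and lysosome, 0.0053 for oxidative phosphorylation, 0.05 for ribosome biogenesis, -0.31 for 5 replication-dependent histone genes, 0.02 for ferroptosis and iron and 0.10 for immune cell markers. Hist1h2ag was past 2-fold at 1.71 (0.44 to 3.35). Metallothioneins (2 measured genes), keratinocyte differentiation (2), endothelial markers (1) and melanocyte markers (1) were not tested.

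**Figure D4:**
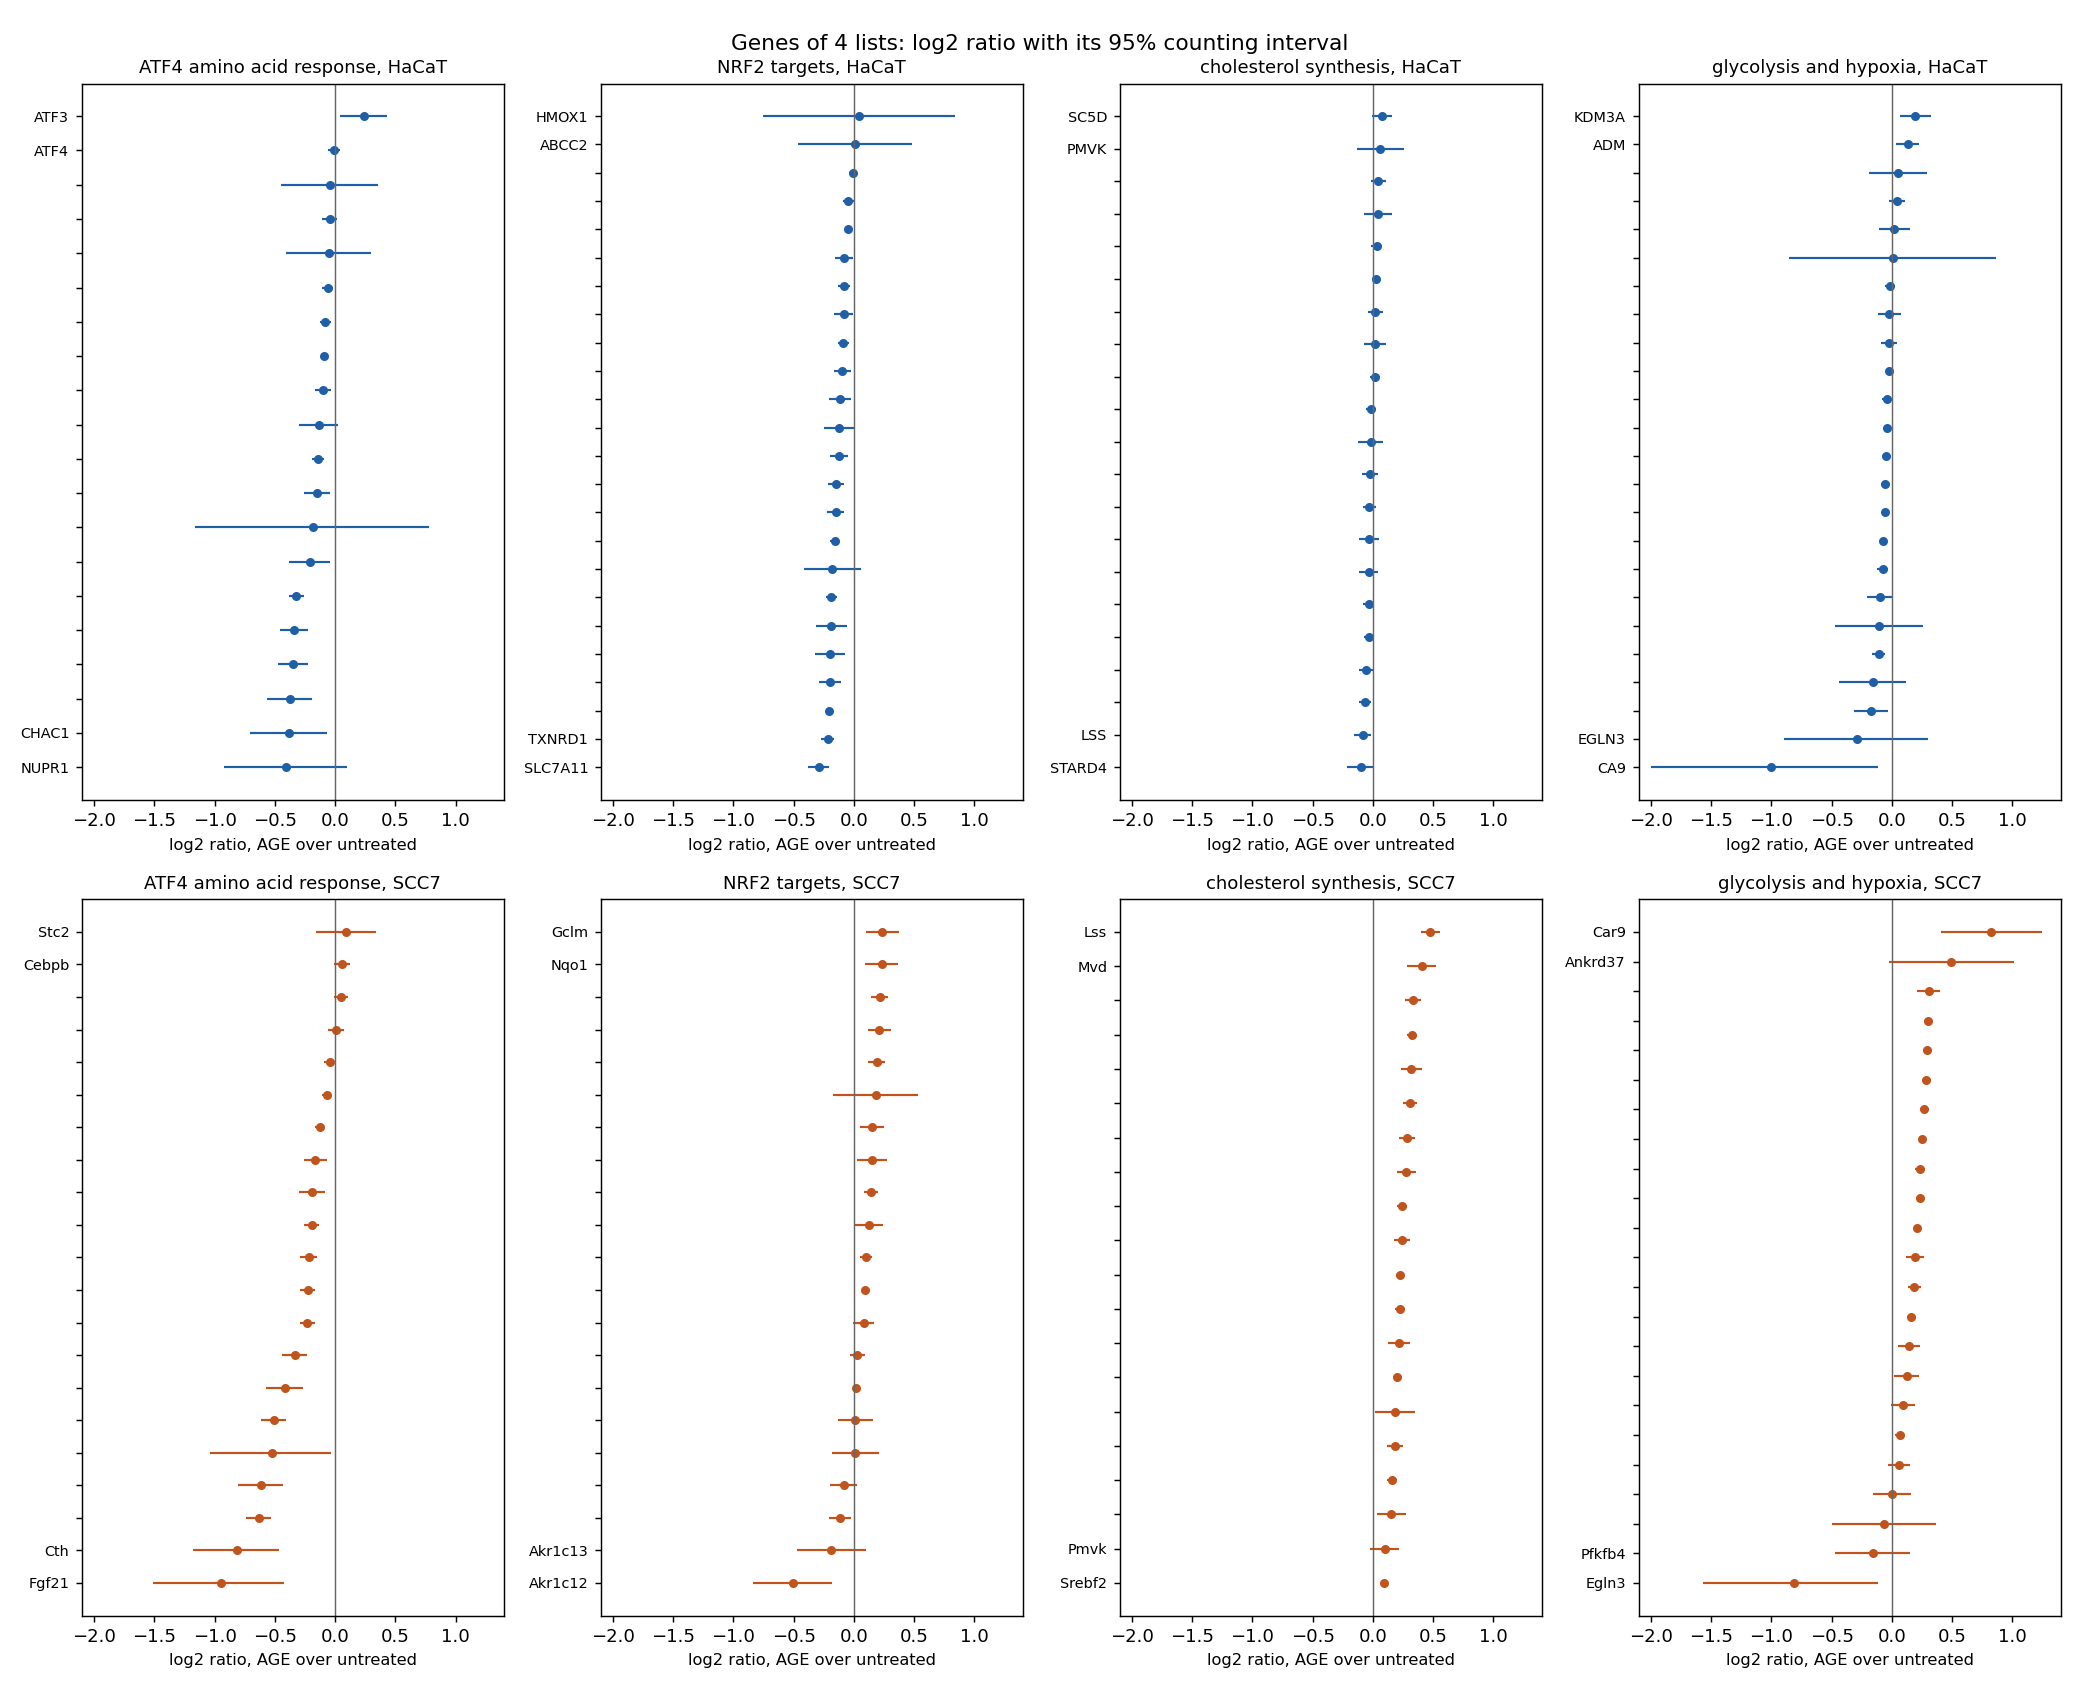
Points give the log2 ratio (AGE over untreated) of each measured gene of 4 lists in HaCaT (upper row of panels) and SCC7 (lower row), the lines give 95% counting intervals, and names are given for the highest and lowest points only. Genes of the ATF4 list lie mostly below 0 in both lines, with medians of -0.14 and -0.22, whereas cholesterol synthesis genes have a median of -0.02 in HaCaT and 0.23 in SCC7.

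Gene by gene, 115 of 11897 tested SCC7 genes differed at least 2-fold with an interval excluding equality, 55 higher and 60 lower, where counting noise alone gave a mean of 25.9. The highest were Gm20388, with 301 reads against 0 and at least 126-fold higher against a floor of 3 reads and 50.6-fold by the interval on pairs, and Gm2004 (5.91, 4.58 to 8.44), both with almost no uniquely mapped reads. Gm28048, Gm14296, Prl2c2 and Gm9803 also had shares of unique reads below 90%, and their values are uncertain. Gm14296 was lower on uniquely mapped reads (-0.11) and Gm9803 was lower on junction reads (-1.49). Among genes with nearly all reads unique, the acute-phase protease inhibitor Serpina3n had 274 reads with AGE and 107 without (1.67, 1.22 to 2.17). The integrin Itgb7 (0.94, 0.70 to 1.18), the adaptor Fyb (0.82, 0.53 to 1.11), the endothelial lipase Lipg (0.89, 0.47 to 1.33), Atg9b, an autophagy gene (0.69, 0.53 to 0.86), and Arhgap6 (0.84, 0.42 to 1.28) made up the rest of the 12. Protein-coding genes with mostly unique reads that followed them were Wwc1, Car9, Dock8, Lss, the proteoglycan Vcan (0.44, 0.36 to 0.52) and Lrp8.

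On the lower side of SCC7, Pagr1a (-5.34, -7.83 to -3.96), Gm14419 and Rnaset2b had few unique reads. The small proteoglycan Fmod had 114 reads with AGE and 379 without (-1.40, -1.86 to -0.97), the calcium pump Atp2a3 had -1.42 (-1.95 to -0.93) and the corneodesmosome gene Cdsn -1.29 (-1.65 to -0.94). Acta2 (1124 reads against 2692), Smim1, Mfsd4b4, the muscle filament gene Des (-0.79, -1.12 to -0.48), the cystathionine lyase Cth (-0.81, -1.18 to -0.46) and the growth factor gene Igf1 (-0.69, -0.87 to -0.51) completed the 12. Smim1 had -0.79 (-1.03 to -0.55) on exon reads but 0.21 on junction reads. Junction reads were few for Cdsn (8 with AGE and 10 without) and Mfsd4b4 (11 and 11), and did not show the fall seen on exon reads. They were 14 and 24 for Fmod and 22 and 62 for Atp2a3. Among protein-coding genes with mostly unique reads, Trib3, Fam20a, Trp63 and Acox2 came next. Of the 115 genes, 44.3% had under 90% unique reads, against 10.8% of all tested genes.

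Between the lines, the log2 ratios of 9014 genes with the same symbol were nearly unrelated across genes, with a Pearson r of -0.00703 and a Spearman rho of -0.0228. Genes are not independent replicates, and matching by symbol is not an orthology table. PCDHGB6, a clustered protocadherin, was the only gene past 2-fold in both lines, higher in HaCaT (1.09, 0.37 to 1.89) and lower in SCC7 (-1.08, -2.13 to -0.17). Independent lists would give 0.0187 genes in that combination. PCDHGB6 had few reads, 97 with AGE and 47 without in HaCaT, and 27 and 73 in SCC7. Counting noise moves the ratios of such genes most, so 0.0187 does not measure how unusual this gene is. With intervals in place of the 2-fold threshold, 139 genes were lower in HaCaT and higher in SCC7, where independence would give 82.9, and 86 were lower in both, where it would give 74.0. A further 83 were higher in HaCaT and lower in SCC7 (63.1 for independence), and 58 were higher in both (70.7). An interval excludes equality more easily for a gene with more reads, and expression level was not matched between the lines. Counts above independence therefore need not reflect AGE.

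Of 31 lists tested in both lines, 14 had medians of the same sign. The ATF4 response and the p53 targets were lower in both lines and the S phase genes higher in both, but of these only the ATF4 call held in both lines in each alternative run for lists, as the HaCaT calls of p53 targets and S phase genes ended on junction reads. NRF2 targets, fatty acid synthesis and glycolysis and hypoxia genes were lower in HaCaT and higher in SCC7, while mitochondrially encoded and ribosomal protein genes were higher in HaCaT and lower in SCC7. Of these, only the calls of NRF2 targets and mitochondrially encoded genes held in both lines in each alternative that gave a value. The HaCaT calls of the other lists ended in some alternatives, and the HaCaT ribosomal protein median changed sign on TPM and on total counts. NRF2 target genes with intervals on opposite sides included TXNRD1 (-0.22 in HaCaT, and 0.10 for Txnrd1 in SCC7) and GCLM (-0.15, and 0.24 for Gclm). These differences between lines were not tested, since each line has a single pair of libraries.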

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

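The test on RNA polymerase III genes was chosen only after the result was seen. The difference between the lines was not tested for any list named here, since each line has a single pair of libraries.

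In HaCaT with AGE, intron reads made up 10.04% of gene reads, against 5.20% in untreated HaCaT, in a column outside the main comparison. The 50 genes with most intron reads held 2357857 intron reads with AGE and 282325 without, while all other genes held 1890096 and 1881111. NRF2 targets had medians on opposite sides of 0 in the lines, with a HaCaT minus SCC7 difference of -0.22. For fatty acid synthesis the difference was -0.19. For glycolysis and hypoxia genes it was -0.23. For mitochondrially encoded genes it was 0.35. For ribosomal protein genes it was 0.0857.

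RNA without a poly(A) tail was higher in the HaCaT AGE library, and the added intron reads lay in few genes. The gene with most intron reads in both HaCaT libraries was ANKRD30BL, with 480521 with AGE and 30308 without. ANKRD30BL spans a ribosomal RNA-like gene, so its added intron reads may belong to the same pattern. Whether the other added intron reads lay in such genes was not tested. Higher transcription by RNA polymerase III alone would not cover the whole pattern. The 4 tested genes annotated as ribosomal RNA outside mitochondria, all of the 5.8S kind made by RNA polymerase I, were higher too. Their median log2 ratio was 5.14 (4.74 to 5.48), beside 4.79 (2.09 to 6.38) for the 5 RNA polymerase III genes. These 4 genes were among the 12 ranked highest, so their values are no separate check of the pattern. Less complete poly(A) selection in that library may account for it, since replication-dependent histone genes, whose RNA mostly lacks a tail, had a median of 0.25, outside the random range, though far below that of the other RNAs. Those SCC7 genes of the same kinds that were looked at singly were not higher to that extent. Their log2 ratios were -0.13 for CT010467.1, -0.75 (-1.37 to -0.17) for the 5.8S gene n-R5-8s1, 0.22 for Rn7sk, -0.20 for Rn7s1 and -0.10 for Rn7s2. Rpph1 and Rmrp, the mouse partners of RPPH1 and RMRP, were not among them. An effect of AGE on these RNAs in HaCaT stays open and untested, as treatment and library coincide.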

How the results depend on the processing

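Alternatives on exon plus intron reads, genes with 90% or more unique reads, junction reads, a lower threshold than 1.5-fold and intervals on pairs were chosen after seeing the data. No paired analysis was possible because each group has 1 library and no model was fitted. Scaling by DESeq2 size factors, total counts or TMM without the 50 most abundant genes kept the counts of genes past 2-fold within 1.5 times, as did both prior counts, intervals on pairs and exon plus intron reads. Of the lists that stood apart, 3 of 12 in HaCaT (NRF2 targets, ATF4, mitochondrially encoded genes) and 9 of 16 in SCC7 kept their call and the sign of their median in each alternative run for lists that gave a value. Keratinocyte differentiation in HaCaT also stayed outside the random range in each, and only its sign changed on TPM. The counts of genes follow the filter, the threshold and, on TPM, the lack of an interval by construction, as fewer genes are tested or more can pass. The cause of the other changes was not tested, except that the HaCaT medians that changed sign on TPM or total counts carry the shift of all genes in that setting (-0.15 and -0.0166).

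In HaCaT, 220 genes were past 2-fold (146 higher, 74 lower). With no filter these were 1302 (720 and 582), with CPM of 5 or more 42 (35 and 7), at 1.5-fold 549 (317 and 232), at the lowest threshold 1025 (586 and 439) and on TPM 578 (297 and 281). They were 131 on uniquely mapped reads (32 lower), 121 among protein-coding genes (83 and 38), 87 among genes with 90% or more unique reads (66 and 21), and 147 lower on junction reads. In SCC7, 115 (55 and 60) became 821 (400 and 421) with no filter, 12 (6 and 6) with CPM of 5 or more, 365 (158 and 207) at 1.5-fold and 862 (374 and 488) at the lowest threshold. On TPM 93 were lower, among protein-coding genes 36 were higher, among genes with 90% or more unique reads 64 (28 and 36) were past 2-fold, and on junction reads 236 (97 and 139).

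On junction reads 5 lists stood apart in HaCaT and 9 in SCC7, among them metallothioneins in HaCaT and Wnt and Notch targets in SCC7, which had no call on exon reads. The HaCaT medians that lost their call on them were -0.0581 for heat shock, -0.0275 for p53, 0.0272 for S phase, -0.0387 for glycolysis and hypoxia, 0.0644 for immediate early, 0.0148 for ribosomal protein and 0.21 for histone genes. In SCC7 those were 0.0547 for glutathione enzymes, 0.0681 for both basal keratinocyte genes and keratinocyte markers, -0.0634 for EMT genes, 0.0890 for fibroblast markers, and with the sign reversed 0.0208 for TGF-beta targets and -0.0952 for AHR genes. Among genes with 90% or more unique reads the medians that lost their call were -0.0439 for HaCaT fatty acid synthesis, 0.0628 for SCC7 glutathione enzymes and 0.0676 for SCC7 AHR genes, and on uniquely mapped reads 0.0645 for SCC7 AHR genes. On TPM, calls were lost at 0.0866 for basal keratinocyte genes, -0.0274 for EMT genes and 0.13 for keratinocyte markers in SCC7. HaCaT medians with the sign reversed on TPM were -0.12 for S phase, -0.0716 for immediate early, -0.0217 for keratinocyte differentiation and -0.14 for ribosomal protein genes, the last also at -0.00021 with total counts.

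Of the genes named in either ranking, KCTD7 changed sign on uniquely mapped reads (0.24), as did Gm14296 (-0.11), and on junction reads FAF1 (-0.0051), SYNGR3 (-0.89), Gm9803 (-1.49) and Smim1 (0.21) did. Lists with no call gained one in 8 cases and stayed without in 273. Those in HaCaT were EMT genes with CPM of 5 or more (0.0418) and among genes with 90% or more unique reads (0.0527), metallothioneins on junction reads (0.15) and, on TPM, metallothioneins and ER chaperones. In SCC7 they were Wnt and Notch targets on junction reads (-0.24) and, on TPM, interferon-stimulated genes and histone genes. The correlation between lines lay between -0.0238 and 0.0154 over the 7 alternatives.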

Other observations

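The genes of this paragraph were picked after their values were seen. Among SCC7 genes of small leucine-rich proteoglycans, which bind collagen fibrils, Fmod (-1.40, interval -1.86 to -0.97), Omd (-0.64, -0.89 to -0.39), Prelp (-0.55, -0.63 to -0.46) and Ogn (-0.55, -0.63 to -0.46) were lower with AGE, Bgn was lower by less (-0.15, -0.18 to -0.13), and Dcn was higher (0.42, 0.29 to 0.54). Neutrophil-attracting chemokines Cxcl1 (0.42, 0.31 to 0.54) and Cxcl5 (0.40, 0.20 to 0.60) and the protease inhibitor Slpi (0.43, 0.30 to 0.57) were higher, while the fixed list of inflammatory cytokines and NF-kB targets lay inside the random range (median 0.03, percentile 75.4). In HaCaT the transferrin receptor TFRC was higher (0.20, 0.17 to 0.24) and the ferritin chains FTL (-0.16, -0.20 to -0.13) and FTH1 (-0.05, -0.06 to -0.04, with 61.0% unique reads) were lower, while the fixed list of ferroptosis and iron genes lay inside the random range (median 0.00076, percentile 57.8). The chemokine CCL2 (0.43, 0.26 to 0.60) and the leukocyte actin-bundling gene LCP1 (0.71, 0.31 to 1.13) were higher in HaCaT.

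The tests on genes with fewer than 10 junction reads and on genes with 10 or more in the untreated library were chosen only after the result was seen. Of the 83 protein-coding HaCaT genes at least 2-fold higher, 37 had 10 or more junction reads, and their junction reads had a median log2 ratio of 1.29, against 1.24 for exon reads. That choice favours genes whose junction reads were higher, and for the 18 genes with 10 or more in the untreated library alone the median was 0.87, between the limits of 0.5 and 1 set for the test. For the other 46, of which 15 are histone genes, the test is void because they were set apart by their few junction reads. Over these genes as a set, ribosomal RNA-like stretches inside exons therefore cannot be told apart from a real difference. Single genes differed. The junction reads of FAF1 (log2 ratio -0.0051) and SYNGR3 (-0.89) did not rise with their exon reads, while FGF2 had 27 junction reads with AGE and 11 without. Reads shared with near-identical genes may account for part of the 83, since 50.6% of them had under 90% unique reads, against 14.0% of tested protein-coding genes. An effect of AGE on the rest stays open and untested.

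Genes of the ATF4 amino acid response were lower with AGE in both lines. With the trend of the log2 ratio on exon length taken out, the list stayed below every random list in both lines (percentile 0), and in HaCaT it did so with the trend on transcript GC content taken out (percentile 0, with a GC value for all 20 genes), so neither trend is the whole reason. GC content in SCC7 was not tested, and a difference in culture, such as medium or density, could not be tested with 1 library per group. A lower amino acid response with AGE may be a candidate explanation, as a hypothesis found and tested on the same 4 libraries. Replicate cultures of each group, with ATF4 protein measured in each, would test it.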
